A study of Arabidopsis thaliana with 6 samples.

How the data were processed

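RNA of Arabidopsis thaliana suspension-cultured cells was measured on 6 Affymetrix ATH1 arrays, 3 of control cultures and 3 of cultures with 0.1 mM isoxaben in the treatment label. Per the labels' protocols, total RNA was extracted with a Qiagen kit, primed with oligo-dT carrying a T7 promoter and labelled as biotinylated cRNA. The deposited table gives 1 linear signal intensity for each of 22810 probe sets on each array, with no detection calls. The algorithm that made these signals from the probes is not given in the sources used here. The deposited intensity values had already been scaled, since the mean after trimming 2% at each end was 100.006 to 100.008 on every array. Each array held 506944 cells per the labels, and the number of arrays limits the precision.

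Groups came from the sample titles and the treatment label. The titles also split the arrays into 2 sets: the first held 1 control and 1 isoxaben array, the second held 2 of each. The labels give replicate numbers for the second set, and the first pair was numbered 1. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. For isoxaben replicate 1, the source name carries the code DCB, while its title and treatment label name isoxaben. It was kept in the isoxaben group, as its treatment label says. No pair of arrays shared more than 1.44% of exactly equal values, so each array counted as 1 sample. Samples with the same number deviated together from their group means, with correlations over probe sets of 0.207, 0.110 and 0.128. Arrays of the second set with different numbers reached 0.101 and 0.118, so the pairing seen in the values follows the title set as much as the number.

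The 64 control probe sets were left out. Values were taken as log2(signal + 16), and fold changes are on that scale, which understates the change of dim genes. Probe sets whose mean log2 value lay below the 40th percentile were dropped, which put the filter at a signal of 22.1 and left 13648 probe sets. Isoxaben was tested against control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, 3 arrays against 3, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene names came from the platform annotation and were updated through gene identifiers with a RefSeq table of the TAIR10.1 assembly (13436 probe sets updated, 77 kept with the annotation's own name). Of all probe sets, 13513 had 1 gene, 503 had several and 8730 are unnamed here. Probe sets with several genes or no name were tested and counted but never named after a gene. The primary-wall cellulose synthases were unnamed here, so no value is given for them.

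The main test, the alternatives, 33 gene lists and the rule for named genes were written before the data were examined. Because few members of those lists had a named probe set, only 8 lists reached 3 tested genes. A further 24 lists were drawn up from family loci (4 lists) or from name patterns in the annotation. The loci came from background knowledge, and only loci that carry a name in the RefSeq table could be checked: a family name was found for 34 of 195 ribosomal protein loci (42 named), 14 of 73 peroxidase loci (16 named), 14 of 41 pectin methylesterase loci (16 named) and 7 of 66 pectate lyase and polygalacturonase loci (8 named). This was done after the annotation, the control probe sets and the total number of calls had been seen, and before the change of any single gene was looked at. Of these, 22 reached 3 tested genes. Of the 713 entries in the lists written first, 45 that only shared letters with a family or lay in the wrong genome were removed in the same way. Another 4 lists, given only among the closing observations, were written after gene values had been seen. Lists were tested with limma's camera (preset correlation 0.01, two-sided), with camera using an estimated correlation, and with fry. Adjustment was separate for the lists written first, the 24 further lists and the last 4. The highest probe set stood for a gene with several (144 genes). The background was the 7503 genes so measured. Ribosomal protein and other family genes have close paralogs, whose RNA can bind to 1 another's probes.

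Named genes were the 8 largest rises and 8 largest falls past the threshold whose groups did not overlap, counting only genes with a name other than their locus. To these were added up to 3 members with the smallest p of each list written first that passed or had a member past the threshold. Other list members are named as examples chosen after their values were seen. Alternatives were quantile normalization, centring on the median, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, a single prior variance, array weights, the mean of a gene's probe sets, blocks for replicate and title set, each title set alone, and leaving out each array. The list counts within the second title set and without control replicate 1, the interaction of title set and treatment, the ranks at other pseudocounts and the direction in the first set of calls from the second were chosen after seeing the data. The fit was tested on simulated data with the spread of the 13648 real probe sets and 200 changed ones. It recovered 17.9% of log2 changes of 0.5, 64.2% of changes of 1 and 95.5% of changes of 2, and 4.07% of its calls were false. Only those 200 were changed there, while 56.6% of probe sets were called in the real data. Its noise was drawn independently for each probe set and array, without deviations shared by an array or title set. These rates therefore need not hold for the real fit. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.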

Results

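The series asked about the assembly of the pectic matrix of the plant cell wall. It compared cultured Arabidopsis cells with cells given isoxaben, a herbicide that blocks cellulose synthesis. Cells grew in suspension in Murashige and Skoog medium with sucrose, a synthetic auxin and the cytokinin kinetin. Transcripts were measured on 3 control and 3 isoxaben arrays, and the labels give no length of treatment. They do not say whether the cells met isoxaben briefly or had been adapted to growth with it, so each change below is a difference between these cultures. The median signal of an array was 31.6 to 42.0. Over the tested probe sets, arrays of 1 group correlated at 0.956 to 0.992 across probe sets, and arrays of different groups at 0.745 to 0.773. The first principal component held 86.8% of the variance and parted the groups. Isoxaben replicate 1, whose source name carries the code DCB, correlated at 0.979 and 0.977 with the other isoxaben arrays and at 0.749 to 0.763 with the controls. A treatment with similar effects could correlate alike, so these values do not settle which treatment that array had.

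The comparison of isoxaben with control cultures asks how transcription differs between cells grown with and without an inhibitor of cellulose synthesis. GH3.3, whose product conjugates auxin to amino acids, rose from a signal of 1.43 ± 0.929 (SD, n = 3) in control to 761 ± 20.1 (SD, n = 3) in isoxaben cultures. HAT2, an auxin-inducible homeodomain transcription factor, rose from 46.3 ± 6.83 to 652 ± 33.4. ATSPS4F, a sucrose-phosphate synthase, fell from 422 ± 23.2 to 5.93 ± 2.63, and cwINV6, annotated as a cell wall invertase, from 1266 ± 50.5 to 50.8 ± 6.81. XTH19, an enzyme that cuts and rejoins xyloglucan, fell from 398 ± 75.1 to 38.9 ± 6.14.

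On the log2(signal + 16) scale, by which named genes were ranked, the change of GH3.3 was 5.48 ± 0.11 (SE; limma, Benjamini-Hochberg adjusted p = 2.88e-09), and that of HAT2 was 3.43 ± 0.12 (adjusted p = 4.50e-08 in the same limma fit). The other 6 of the 8 largest rises on that scale were LCR69, a small cysteine-rich defensin-like protein (5.14 ± 0.12), 3xHMG-box2, a chromosome-binding protein of mitosis (3.21 ± 0.16), TBL36, of a family of wall polysaccharide acetyltransferases (2.94 ± 0.12), the drought-induced DI21 (2.89 ± 0.14), the peroxidase PRX52 (2.85 ± 0.12) and MGL, a methionine gamma-lyase (2.65 ± 0.11). Among the falls, ATSPS4F changed by -4.33 ± 0.13 and cwINV6 by -4.27 ± 0.11. ZCF37 (-4.14 ± 0.13), SAL2 (-3.96 ± 0.14) and GAT1_2.1, a glutamine amidotransferase-like protein (-3.71 ± 0.12), followed. XTH19 (-2.90 ± 0.16), the linker histone HIS1-3 (-2.66 ± 0.13) and the calmodulin-like CML41 (-2.66 ± 0.22) completed the 8. Probe sets without a gene name or known only by locus were left out of this ranking. Over all probe sets, 38 rose and 76 fell by at least 8-fold, so the lower members of each 8 are not among the largest changes measured. The order depended on the pseudocount. With a pseudocount of 64, LCR69 (4.42) came before GH3.3 (3.66) and cwINV6 (-3.53) before ATSPS4F (-2.80), and with a pseudocount of 1, ZCF37 (-6.33) came before ATSPS4F (-6.02). Of the 8 rises, 5 stayed among the first 8 with a pseudocount of 1 and 6 with 64, and of the 8 falls, 8 and 6. The highest limma adjusted p among these 16 genes was 4.93e-06, for CML41. A passing adjusted p and no overlap between the 3 arrays of each group were conditions for being named among them.

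**Figure D1:**
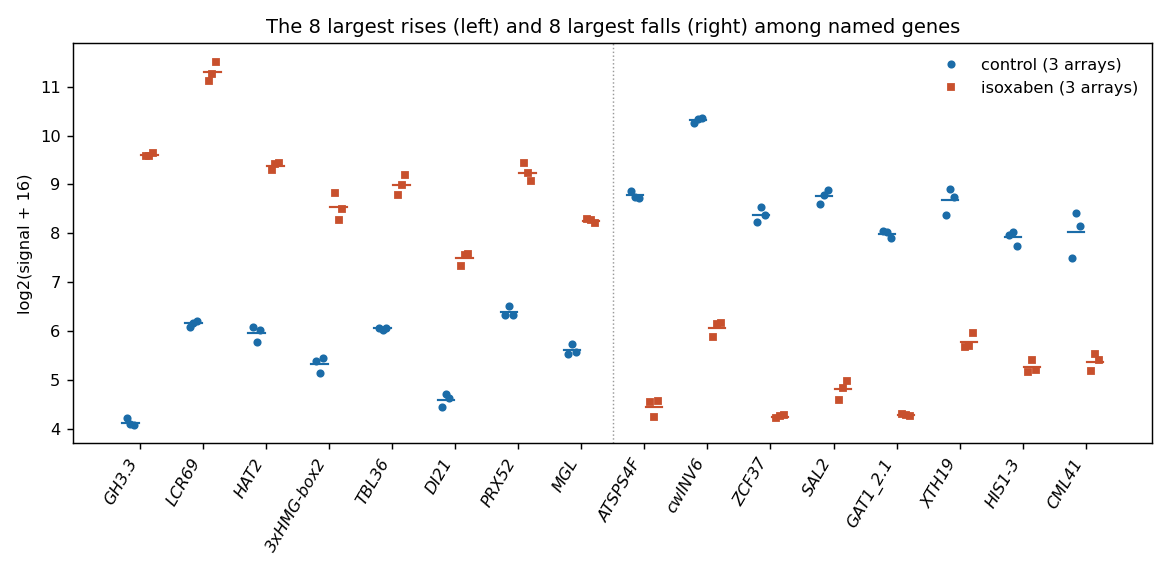
Signals of the 8 largest rises and 8 largest falls among named genes on the log2(signal + 16) scale of the vertical axis, with control arrays as circles, isoxaben arrays as squares and a line at each group's mean of 3 arrays. GH3.3 has a mean signal of 1.43 in control and 761 in isoxaben cultures, and cwINV6 has 1266 and 50.8.

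In total, 4011 probe sets were higher and 3715 lower with isoxaben among 13648 tested (limma, Benjamini-Hochberg adjusted p under 0.05), which is 56.6% of them. Changes of at least 2-fold were found for 1503 of the higher and 1354 of the lower ones. The groups did not overlap for 63.2% of probe sets, where chance gives 10%. The median log2 change over all probe sets was 0.00824 and the median SE 0.142. With title set as a block the counts were 4510 and 4144, and within the second set alone (2 against 2) they were 4832 and 4193. The first set holds 1 array of each group and allows no test. Of the 9025 probe sets called in the second set alone, 92.7% had the same direction in the first. Among the called probe sets, 1752 higher and 1663 lower ones are unnamed here.

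Most tested genes on the lists of pectin methylesterases and of xyloglucan endotransglucosylase/hydrolases, which act on wall polysaccharides, were lower. On the list of pectin methylesterases, which remove methyl groups from pectin, and their inhibitors, 3 of 21 members were tested and all 3 fell. They were PMEPCRF (892 ± 37.3 to 174 ± 41.5; log2 change -2.28 ± 0.16), ATPMEPCRB (-0.71 ± 0.11) and PME61 (-0.53 ± 0.16). Of 4 xyloglucan endotransglucosylase/hydrolases, 3 fell: XTH19, XTH18 (1132 ± 217 to 467 ± 16.6; -1.23 ± 0.14) and EXGT-A3 (-0.38 ± 0.09), while XTH20 (-0.33 ± 0.28) did not pass. The counts adjusted over the list alone were also 3 and 3. CSLC04, a glucan synthase of the xyloglucan backbone, fell by 0.70 ± 0.12, the only call among 7 cellulose synthase-like genes, and also the only 1 adjusted over the list alone. ATCSLC08 (0.32 ± 0.16) and CSLC12 (-0.34 ± 0.21) did not pass. GAUT15, of a family of galacturonosyltransferases, rose by 0.67 ± 0.12 and was the only tested member of its pectin synthesis list. The expansins, which loosen walls, split: EXPA4 rose by 2.38 ± 0.19, EXLA2 (-0.88 ± 0.18) and EXLA1 (-0.32 ± 0.11) fell, and 3 did not pass (the same counts adjusted over the list alone).

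With limma's camera and Benjamini-Hochberg adjustment over the 8 lists, the shift passed for xyloglucan endotransglucosylase/hydrolases (median log2 change -0.81, adjusted p = 0.0364) and for pectin methylesterases (-0.71, adjusted p = 0.0412). Neither held with an estimated correlation (adjusted p = 0.232 for each). Of 33 xyloglucan endotransglucosylase/hydrolases on the list, 10 had a probe set named here, and the filter on dim probe sets left 4. With no filter their median was -0.21 (camera adjusted p = 0.0962), and with the 60th percentile filter -1.23 (0.0523). With title set as a block, camera's adjusted p was 0.0372 for the first list and 0.0519 for the second. Within the second title set, it was 0.0533 for each, with medians of -0.90 and -0.82, and the first set gave medians of -1.14 and -0.86 without a test. The shift did not pass for cellulose synthase-like genes (median -0.04, adjusted p = 0.744) or expansins (median -0.06, mean 0.22, camera direction down, adjusted p = 0.908). In the title set block these had camera adjusted p = 0.676 and 0.859. Medians in the second and first set were -0.02 and -0.08 for the cellulose synthase-like genes, and 0.03 and -0.23 for the expansins. The limma call of PME61 was lost without isoxaben replicate 1 (adjusted p = 0.0696) or 2 (0.0707), with no filter (0.0528) and within the second title set (-0.37, 0.0596). That of EXLA1 was lost without any array except isoxaben replicate 3, with limma adjusted p up to 0.114, and also with no filter (0.126), with a single prior variance (0.0626) and within the second title set (-0.20, 0.159). COB, needed for oriented cellulose deposition, changed by -0.29 ± 0.17 and did not pass (limma adjusted p = 0.169). It was called lower within the second title set (-0.31), but not without control replicate 1 (-0.15).

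Lists of pectin-active families were also drawn up by locus from background knowledge, and few of their loci carry a family name that could be checked (7 of 66 for pectate lyases and polygalacturonases, 14 of 41 for pectin methylesterases). Of 17 pectate lyases and polygalacturonases, enzymes that cleave pectin, 10 rose and 1 fell, with a median log2 change of 0.86. Among the rises, AT3G53190 went from a signal of 46.4 ± 21.2 to 663 ± 31.2 (log2 change 3.50). AT3G15720 went from 10.3 ± 3.21, below the filter signal of 22.1, to 226 ± 7.81, so its log2 change of 3.21 depends on the pseudocount. The fall was AT1G56710 (-1.07). The shift had a camera adjusted p of 0.00218, with adjusted p = 0.271 with an estimated correlation. These 17 were what the filter on dim probe sets left of 51 with a probe set named here, and with no filter the median was 0.03 (camera adjusted p = 0.234). Of 8 pectin methylesterases by locus, AT3G43270 rose (0.79 ± 0.16), 5 fell and 2 did not pass (median -0.62, camera adjusted p = 0.0789, and 0.393 with an estimated correlation). With no filter their median was -0.09 (camera adjusted p = 0.234). This list overlaps the shorter list of pectin methylesterases above, as its lowest change (-2.28) is that of PMEPCRF, so the falls of the 2 lists are not separate evidence. Within the second title set, 12 and 3 of the lyases and polygalacturonases were higher and lower (median 0.72, camera adjusted p = 0.00749, and 0.00491 with the set as a block). The pectin methylesterases had 1 higher and 4 lower there (median -0.59, 0.110, and 0.0993 with the block). Medians in the first set were 1.38 and -0.67.

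Among peroxidases, glutathione transferases, WRKY factors and the other listed genes that follow, the directions differed. Of 5 class III peroxidases, PRX52, AT2G41480 (57.8 ± 13.4 to 485 ± 112; log2 change 2.76 ± 0.18) and PRXR1 (0.39 ± 0.13) rose, and none fell. Adjusted over the list alone, 3 rose and 1 fell. On the wider list of peroxidases by locus, 9 of 25 rose and 5 fell (median 0.01). The 2 lists overlap, as the highest change of the wider one (2.85) is that of PRX52. All 4 tested glutathione transferases, which conjugate glutathione to foreign and reactive compounds, fell (also 4 adjusted over the list alone), led by GSTU27 (1728 ± 136 to 564 ± 90.7; -1.60 ± 0.13), then GSTU15 (-0.95 ± 0.15) and GSTL3 (-0.54 ± 0.13). The glycosyltransferases UGT73B5 (0.82 ± 0.15) and UGT73B4 (0.43 ± 0.13), of the xenobiotic response list, rose. Of 72 WRKY transcription factors on the list, 6 were tested. ZAP1 (-0.99 ± 0.12), WRKY53 (-1.27 ± 0.18) and WRKY20 (-0.40 ± 0.11) fell and the other tested ones did not pass, the same adjusted over the list alone. CCR2, a cinnamoyl-CoA reductase of lignin synthesis, fell by 2.01 ± 0.14, while HCT changed by -0.00 ± 0.11. Hsp70-2, a chaperone, fell by 0.58 ± 0.17. FER, a receptor kinase that senses the wall, fell by 0.36 ± 0.11, and the related THE1 changed by -0.37 ± 0.15 (limma adjusted p = 0.0629), though both passed when adjusted over the list alone.

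The camera shift passed for glutathione transferases (median log2 change -0.75, adjusted p = 0.0364, but 0.270 as the adjusted p with an estimated correlation). Of 49 glutathione transferases on the list, 14 had a probe set named here, and the filter on dim probe sets left 4. With no filter the median was 0.05 (camera adjusted p = 0.725), so the call was lost and the direction turned. The camera shift did not pass for peroxidases (0.39, adjusted p = 0.0828) or WRKY factors (-0.38, adjusted p = 0.103). The peroxidase list passed camera without control replicate 2 (adjusted p = 0.0494) or 3 (0.0490). Camera with the title set block gave adjusted p = 0.0350, 0.0936 and 0.0936 for the 3 lists in that order. The second title set gave medians of -0.74, 0.32 and -0.42 and the first set -0.80, 0.63 and -0.31. Without isoxaben replicate 2, the limma calls of PRXR1 (adjusted p = 0.102), FER (0.0651) and Hsp70-2 (0.0631) were lost. Without isoxaben replicate 3 they were lost as well (0.0508, 0.0693 and 0.0724), and that of FER also without control replicate 2 (0.0548) or 3 (0.0970). THE1 passed limma without control replicate 1 (log2 change -0.50, adjusted p = 0.00907), without isoxaben replicate 3 (-0.48, 0.0434), with array weights (-0.59, 0.000164), within the second title set (-0.50, 0.00917), with the title set block (-0.37, 0.0343) and with the replicate block (-0.37, 0.0341). Centring arrays on their medians ended the limma calls of PRXR1 (adjusted p = 0.133), FER (0.0608) and UGT73B4 (0.0851).

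Most tested photosynthesis genes of the nucleus were higher, though only 7 of 49 on the list had a probe set named here. Of 5 tested, 4 rose (also 4 adjusted over the list alone), among them PSAE-1 of photosystem I (11.0 ± 7.83 to 137 ± 9.38; log2 change 2.54 ± 0.19), and PSBW (2.35 ± 0.13) and PSBY (2.00 ± 0.12) of photosystem II. All control signals of PSAE-1 lay below the filter signal of 22.1, so its log2 change depends on the pseudocount. The shift of the list had a camera adjusted p of 0.00786, with adjusted p = 0.232 with an estimated correlation. With the title set block camera gave 0.0137, and the medians were 2.02 within each title set. Plastid-encoded genes moved with them. Of 41 plastid photosynthesis genes 25 rose and 3 fell (median 0.85, camera adjusted p = 0.000471, estimated correlation adjusted p = 0.393), with psaB (2.37) and psbH (2.36) at the top and petD (-2.11) and psbN (-1.91) at the bottom. Of 19 plastid genes for transcription and translation 16 rose and 1 fell (median 1.42, camera adjusted p = 7.89e-05, estimated correlation adjusted p = 0.407), led by rpoC2 (2.41). The control probe set for 25S ribosomal RNA, which was outside the limma fit, had a mean signal of 6.27 ± 1.21 (SD) in control and 31.4 ± 16.2 in isoxaben arrays (exact permutation test, two-sided, p = 0.1, the smallest p that 3 against 3 arrays allow). Its signals on the control arrays (4.9 to 7.2) and on isoxaben replicate 2 (17.6) lay below the filter signal of 22.1. Of 11 mitochondrial genes, 2 rose and 2 fell (median -0.28, camera adjusted p = 0.896). Within the second title set 4 were higher and 5 lower (median -0.24). Without control replicate 1 the counts were 3 and 2, and the median turned to 0.06.

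Genes listed as cytosolic ribosomal proteins were mostly higher. The list was drawn up by locus from background knowledge, and 34 of its 195 loci carry a family name that could be checked. Of 111 tested, 109 rose and none fell, with a median log2 change of 1.46 and a range of 0.12 to 2.90 (camera adjusted p = 2.29e-32). With an estimated correlation the adjusted p was 0.271. PRL, a replication licensing factor and the only tested member of the cell division list, rose from a signal of 173 ± 4.99 to 518 ± 52.6. In the list of mitosis and spindle genes 10 of 15 rose and 2 fell (median 1.12, camera adjusted p = 0.0272, estimated correlation adjusted p = 0.271). AUR1, a mitotic kinase, changed by 2.17 and TOPII, a topoisomerase, by 2.56, while the cytokinesis gene KEU (-1.24) and ATMAP65-6 (-1.40) fell. Of 10 autophagy genes, ATG8 family members and ATG3, 9 fell (median -0.82, camera adjusted p = 0.000602, estimated correlation adjusted p = 0.407), with ATG8H at -1.73 and ATG8F at -1.61.

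Serine carboxypeptidase-like genes rose in 6 of 9 cases and none fell (median 1.05, camera adjusted p = 0.00968, estimated correlation adjusted p = 0.271). Those 9 were what the filter left of 29 with a probe set named here, and with no filter the median was 0.01 (camera adjusted p = 0.348). Calmodulin-like genes fell in 4 of 6 cases and rose in 1, with CML41, CML43 (-1.91), CML37 (-1.67) and CML38 (-1.53) lower and CML23 (1.07) higher (median -1.60, camera adjusted p = 0.0432, estimated correlation adjusted p = 0.407). The calmodulin-like call was lost without isoxaben replicate 1 (median -1.53, adjusted p = 0.0537), with pseudocounts of 1 (-1.69, 0.0928) or 64 (-0.96, 0.0536) and with no filter (-1.53, 0.0568). The call of mitosis genes was lost with a pseudocount of 1 (adjusted p = 0.0602) and with the 60th percentile filter (0.230), though the medians, 1.14 and 1.12, were close to the 1.12 above. Of the 22 further lists tested, 8 passed camera and 14 did not, with adjusted p of 0.0789 to 0.896. Among these were class III peroxidases by locus (9 of 25 rose and 5 fell, adjusted p = 0.669), trichome birefringence-like genes (3 of 10 rose, 0.185), UDP-glycosyltransferases (4 of 15 rose and 2 fell, median 0.01, mean -0.02, camera direction up, 0.896), tubulins (3 of 7 rose and 2 fell, 0.427) and histones (1 of 7 rose and 2 fell, 0.771).

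Within the second title set, the counts higher and lower were 110 and 0 for ribosomal proteins, 29 and 5 for plastid photosynthesis, 16 and 2 for plastid gene expression, 9 and 3 for mitosis, 0 and 9 for autophagy, 6 and 0 for carboxypeptidases and 1 and 4 for calmodulin-like genes. The camera call of mitosis genes was lost there (median 1.13, adjusted p = 0.0725). With title set as a block these 7 lists all passed, with camera adjusted p of 2.45e-31, 0.000165, 2.66e-05, 0.0333, 0.000248, 0.0114 and 0.0392 in that order, all at the preset correlation. With an estimated correlation, over all arrays, none of the 7 passed (adjusted p = 0.271 to 0.407). In the first title set their medians were 1.49, 1.03, 1.30, 0.71, -0.73, 1.03 and -1.43.

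**Figure D2:**
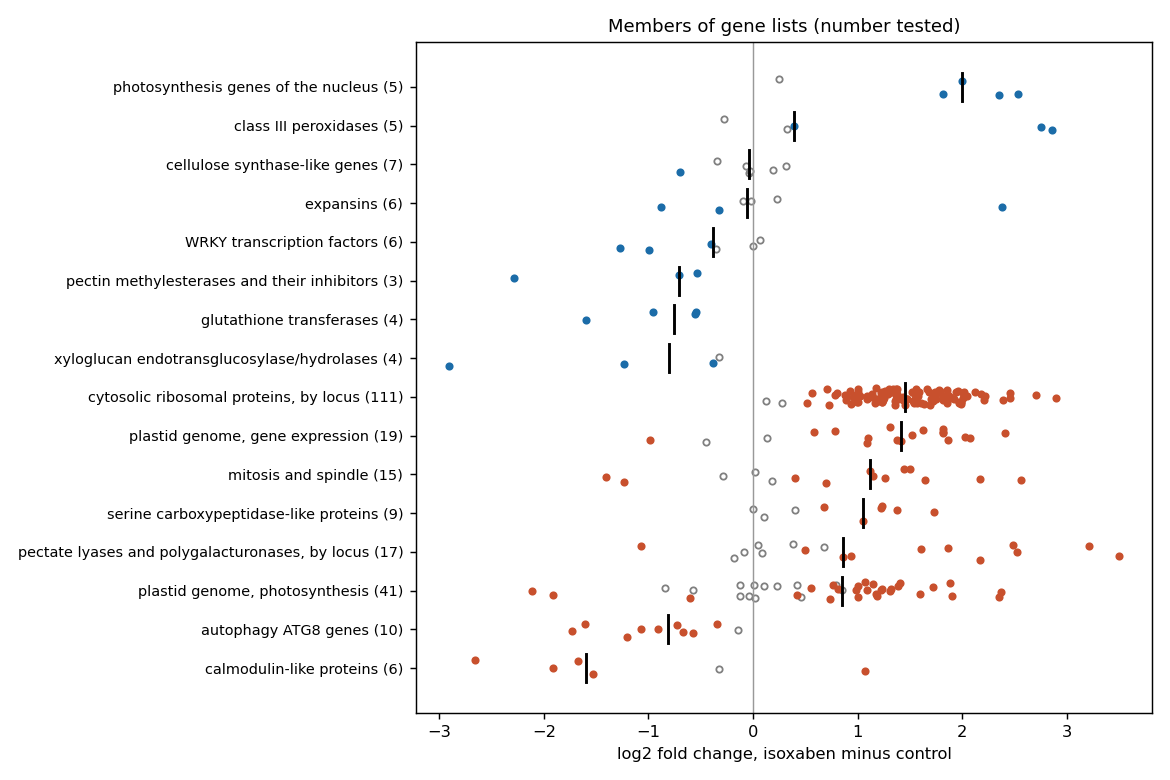
Log2 fold change (horizontal axis, isoxaben minus control) of each tested member of the 8 lists written first (blue) and of the 8 further lists that passed camera (orange), with the number tested in brackets. Filled points passed limma's adjusted p under 0.05, open points did not, and a black line marks the median, 1.46 for the 111 ribosomal protein genes.

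Array quality differed most for control replicate 1. The labels give it 7023 outlier cells (1.39% of its cells) against 160 to 613 on the others, and a background of 67.1 against 84.5 to 113. Its values had an SD of 0.259 (log2) around the group mean, against 0.126 to 0.177 on the other arrays. Without it, 4505 probe sets were higher and 3888 lower (limma, Benjamini-Hochberg adjusted p under 0.05). Ribosomal protein genes then had 109 higher and 0 lower, plastid photosynthesis genes 29 and 4, and autophagy genes 0 and 9. Ratios of 3′ to 5′ probe sets were 1.52 to 2.12 for actin and 1.19 to 1.87 for ubiquitin, with overlapping groups. For GAPDH they were 0.931 to 1.06 in control and 1.08 to 1.17 in isoxaben arrays.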

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

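The interaction test and the tests of title set and of ribosomal RNA below were chosen after the values they rest on had been seen.

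The effect of isoxaben differed between the first and the second title set for 606 probe sets (limma interaction term, Benjamini-Hochberg adjusted p under 0.05), and 3295 had an unadjusted p under 0.05. The first set has 1 array per group, so the fit assumes that these vary like the arrays of the second set. Of the 606, 210 also differed between isoxaben and control over all arrays, and 200 of these had the same direction in both sets. That call rests on both sets, so a shared direction was likely in advance. For the rest of the 606 the direction was not compared. Since the source name of isoxaben replicate 1 carries the code DCB, a different treatment of that array was weighed. Isoxaben replicate 1 lay farther from its group than control replicate 1 did from its own for 15.5% of the 606. Control replicate 1 lay farther for 84.5%, with a median log2 distance of 0.804 against 0.291. A likely source of most of these differences is that array, which also has the most outlier cells. Over all tested probe sets it lay farther as well (0.243 against 0.169), so the interaction favours it whatever isoxaben replicate 1 received. Whether the culture or the hybridization of control replicate 1 differed stays open. The distances cannot tell which treatment isoxaben replicate 1 had, and neither a small difference nor a treatment with similar effects is excluded.

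Control probe sets for ribosomal RNA, which are outside the comparisons of genes, were brighter on every isoxaben array than on any control array. The mean signal was 31.4 ± 16.2 (SD) against 6.27 ± 1.21 for 25S RNA and 38.9 ± 8.63 against 9 ± 3.32 for 5S RNA (exact permutation test, two-sided, p = 0.1 for each, the smallest p that 3 against 3 arrays allow). Plastid transcripts were higher too, and more RNA without a poly(A) tail in the labelled target could raise both, but would raise mitochondrial transcripts alike. The median over genes on each array, each gene centred first, differed between isoxaben and control by -0.19 ± 0.22 (SE, log2) for mitochondrial and 0.78 ± 0.12 for plastid photosynthesis genes. Under that assumption, the gap of -0.97 ± 0.12 argues against such RNA as the whole cause for plastid genes. The medians of the fitted changes were -0.28 and 0.85, and without control replicate 1 they were 0.06 and 1.01. For the ribosomal RNA itself, where 2 of 2 probe sets were higher on all isoxaben arrays, carried-over RNA and more ribosomal RNA per cell cannot be told apart, since either gives brighter probes.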

How the results depend on the processing

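The counts of 4011 higher and 3715 lower probe sets stayed within 1.5 times under all 17 alternatives with a test, from 2952 (60th percentile filter, fewer probe sets tested) to 5258 higher (array weights) and from 2974 to 4613 lower. The replicate block gave 4250 and 3913. Leaving out 1 array gave 3447 to 4505 higher and 3229 to 3888 lower, and no main call was reversed and past the threshold in any of them. The camera calls of lists were less stable, and the cause was not tested except where noted. With an estimated correlation, all 12 list calls of the results were lost (adjusted p = 0.232 to 0.407): those of the 8 further lists that had passed, and those of pectin methylesterases (median -0.71), xyloglucan endotransglucosylase/hydrolases (-0.81), glutathione transferases (-0.75) and nuclear photosynthesis genes (2.00), the medians being those of the same fit. Pectin methylesterases lost the call with title set as a block (-0.71, adjusted p = 0.0519) and in the second set alone (-0.82), where 2 arrays fewer were used. Xyloglucan endotransglucosylase/hydrolases lost it with no filter (-0.21), with the 60th percentile filter (-1.23) and in the second set alone (-0.90), and had -1.14 in the first. Glutathione transferases lost it with no filter (0.0545, adjusted p = 0.725), which adds dim members. The replicate block changed no list call and, among named genes, only that of THE1. fry, which compares a list with no other genes, passed all 12 lists with a camera call in its directional test (adjusted p = 2.01e-05 to 0.0026). As 56.6% of tested probe sets were called, passing fry does not set a list apart from other genes. It also passed peroxidases (0.39) and WRKY factors (-0.38) in its directional and mixed tests, and cellulose synthase-like genes (-0.0384) in the mixed one. Expansins passed both (median -0.0574), with direction up in the directional test against camera's down. Of the 14 further lists that did not pass camera, fry passed 10 in the directional test (adjusted p = 7.38e-05 to 0.0443), among them pectin methylesterases by locus, tubulins and subtilases, and 14 in the mixed one. Expansins had -0.23 in the first set alone. Leaving out 1 array gave medians of 0.285 to 0.463 for peroxidases.

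Of 47 named genes, 43 passed limma, but a passing call or a small p was part of the rule that named them. Over 17 alternatives with a test, none of 789 values reversed past the threshold, 23 lost a call (6 genes) and 6 gained it (1 gene). In the first title set, 30 of 47 values lay within 1 SD (the root of the summed group variances) of the main value and 17 moved by more. The main value and this SD include the arrays of that set, so closeness is partly built in. Signal limits the dim genes: with no detection calls, a control mean such as 1.43 for GH3.3 cannot be told from background, and its fold change depends on the pseudocount.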

Other observations

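The 4 gene lists, the test of RNA integrity and that of growth stage in this part were chosen after gene values had been seen, and the tests of splits and scaling before.

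Most listed genes of membrane sorting and of protein quality control in the endoplasmic reticulum were lower with isoxaben. Of 10 genes of ESCRT-III, which cuts membranes inward at endosomes, and related sorting proteins, 9 fell and 1 rose (median log2 change -1.12), with VPS60.1 at -1.94 and SNF7.2 at -1.64, against VPS2.2 at 2.02. Of 13 genes of endoplasmic reticulum quality control, 8 fell and 2 rose (median -0.89), led by BZIP60 (-1.84), a transcription factor of the unfolded protein response, UBC32 (-1.80) and DER1 (-1.67). Camera gave adjusted p = 0.00123 and 0.00203 over these 4 lists, and 0.0935 and 0.124 with an estimated correlation. As the lists were drawn from these values, the p-values are not independent evidence.

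Most listed auxin-responsive genes and subunits of the nuclear RNA polymerases were higher. Of 7 auxin-responsive genes, 5 rose and 1 fell (median 1.45), among them LBD16 (1.45) and IAA30 (1.52), against IAA18 (-0.99). The highest change on this list (5.48) is that of GH3.3, named above, so the list is not separate evidence on auxin response. These 7 were what the filter on dim probe sets left of 15, and the list was not tested without the filter. Of 12 polymerase subunits, 10 rose and none fell (median 0.64), including NRPA1 (0.99) and NRPA2 (0.94), the large subunits of RNA polymerase I. Camera gave adjusted p = 0.00483 and 0.00184, and 0.0935 for each with an estimated correlation. The medium contained an auxin in every sample.

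Of the tested probe sets, 56.6% differed between the groups, 7726 in all. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many calls, the real one, and the highest of the others gave 0. Each other split mixes control and isoxaben arrays, so the group difference adds to its spread and few calls were likely in advance. With 10 splits the share also cannot fall under 0.05, so the splits do not decide whether the difference arose by chance. Quantile normalization gave 7839 calls and kept 7449 of the 7717 main calls it tested. Centring on the median kept 7038 of 7726, with 3506 probe sets higher and 3809 lower. The choice among these scalings is therefore unlikely as the cause of most calls. All of them assume that the arrays share a mean, a middle or a distribution, so none can show a change in total RNA per cell. Values of isoxaben replicate 2 against control replicate 1, whose actin and ubiquitin ratios run against the groups (1.62 against 2.12, 1.46 against 1.55) and whose GAPDH ratios are close (1.08 and 1.06), argue against RNA integrity as the whole cause: of 7751 probe sets called on the other 4 arrays, 93.3% had the same direction in this pair, with a slope of 0.892 on the change in those 4, while a part stays open, since GAPDH ratios parted the groups. A candidate explanation is that the cultures were at different growth stages at harvest, as 109 ribosomal protein genes rose while autophagy genes fell, which cannot be told apart from an effect of isoxaben on growth or from long adaptation to it, since the labels give neither harvest time, cell density nor length of treatment.

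Among probe sets unnamed here, singled out after their values were seen, 1 changed from 4.43 ± 4.01 to 1216 ± 17.8 and another from 1710 ± 182 to 4.2 ± 2.26 (signal, mean ± SD of 3 arrays). The low values cannot be told from background, so the folds and their ranks depend on the pseudocount. On control replicate 3, the spike-in probe set for the 5′ end of bioD in its older version had a signal of 2173, against 47.7 to 97.5 on the other arrays, and that for cre had 146 against 671 to 1127. The newer versions of the same probe sets had 354.7 and 1680 on that array, against 377 to 639 and 1793 to 2957 on the others.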
